A study of Mus musculus with 9 samples.

How the data were processed

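Sorted TDC, conventional T cells and conventional DC from spleens of naive mice homozygous for the Zbtb46-GFP reporter were profiled, with 3 libraries per population and 9 in all. Per the labels, RNA was extracted with a column kit and libraries were made with the Lexogen QuantSeq stranded kit, which reads near the 3' end of transcripts, so counts follow transcript number with little dependence on gene length, and reads near-identical at their 3' ends cannot be told apart. The deposited table holds whole-number read counts per gene for each library, not normalised. Per the submitters' processing notes, the tools were FastQC, MultiQC, Trimmomatic, STAR and featureCounts, with no versions or settings given. The same notes name the human build hg38, although the samples and the gene symbols of the table are mouse. The build, the annotation and the strand setting of the counting are otherwise not given in the sources used here. Antisense and overlapping genes therefore stay uncertain, as do near-identical copies such as Hbb-bs and Hbb-bt, Hba-a1 and Hba-a2, Hspa1a and Hspa1b, Trbc1 and Trbc2, the Klra genes and class I genes such as H2-Q7.

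The table had 50508 gene symbols, of which 47627 were found in a RefSeq table of the mouse, 23670 had no read in any library and 26 had been turned into dates by a spreadsheet, which hides the genes of the septin and March families. The locus of Zbtb46 was taken from a mouse annotation of GRCm38, since no coordinates are in the table. Library totals ran from 10986544 to 25676640 reads, and a single read was worth 0.0383 to 0.0897 CPM in a library. Fold changes against a group with no reads are given as lower bounds computed with 3 reads over the group. Floors and intervals cover counting error only. Replicates were compared before averaging: chi-square values per degree of freedom between libraries of a group ran from 67.8 to 275, so no library repeated another within sampling noise.

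Tests were run on the counts as deposited with edgeR 4.0.16 (R 4.3.3). Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 14708 genes and at least 99.8% of the reads of each library. TMM factors, a robust quasi-likelihood fit of all 3 groups with 6 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05 were used for DC against T cells, TDC against T cells and TDC against DC. The common biological coefficient of variation was 0.588. Sets above both controls, below both and between them were taken from these contrasts. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on voom values, again with an estimated correlation, and with fry, with adjustment over the 32 lists of a comparison. With simulated counts of the same genes, libraries and spread, the test recovered 1 of 66, 16 of 64 and 49 of 70 genes changed 2-fold, 4-fold and 8-fold for TDC against T cells. For TDC against DC it recovered 1 of 76, 12 of 57 and 55 of 67. It called 2 and 3 genes that had been left unchanged. Each library is a pool of animals, and the labels do not say which animals entered it, so p-values measure the spread between these pools.

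The design, the lists and the alternatives were written before the data were examined. Named genes followed a rule from the same time. For each comparison of TDC with a control, and for the sets above and below both, it took the 10 largest changes among called genes with no overlap between libraries and at least 10 CPM in the higher group, without receptor gene segments and clone-based names. For DC against T cells it took 5 each way, and 1 of them in each direction is not reported here. It added up to 4 members of each list with the smallest adjusted p, and 24 marker genes whatever their result. The 32 lists held 645 genes, of which 641 were found, 1 of them under an older symbol (Cd244a as Cd244), and covered T cell, DC, antigen presentation, myeloid, other blood cell, stroma, cell cycle, stress, cytokine and metabolic genes. Alternatives were DESeq2 size factors, library size and upper-quartile scaling, no filter and a 10 CPM filter, the DESeq2 1.42.0 Wald test, limma-voom, glmTreat against a log2 fold change of 1, fits of single pairs of groups, the replicate number as a block, and leaving out each library and each replicate number. No sample was left out of the comparisons.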

Results

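RNA was measured in 3 cell populations that had been sorted from the spleens of untreated 8-week-old mice homozygous for the Zbtb46-GFP reporter, in which green fluorescent protein marks cells that use the Zbtb46 locus, a locus used by conventional dendritic cells (DC). The population in question was named TDC by the submitters, and conventional T cells and conventional DC served as its controls. The gates of the sort are not given in the sources used here. Each population was represented by 3 libraries, and each library came from the pooled spleens of 5 mice (replicate 1) or 6 mice (replicates 2 and 3). The libraries held 10986544 to 18071425 reads assigned to genes for T cells, 14973484 to 25676640 for DC and 14594850 to 22677130 for TDC. At this depth, 3 reads over a group corresponded to 0.0557 CPM (counts scaled to library size) in T cells, 0.0524 CPM in DC and 0.0706 CPM in TDC, limits that cover counting error only. Ribosomal protein genes took 3.70% to 4.66% of the reads in T cell libraries, 1.14% to 2.55% in DC and 0.461% to 0.941% in TDC. Hemoglobin genes took 0.0501% to 0.144% of the reads in TDC libraries and at most 0.00188% in any control library. Values below are TMM-normalised CPM as mean ± SD (n = 3 libraries in every group), and p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14708 genes unless another test is named.

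The 3 populations separated by their sort labels. Principal component 1 held 54.1% of the variance and placed T cell libraries at -211 to -197, DC at 63.5 to 77.9 and TDC at 125 to 142. Principal component 2 placed DC at -173 to -97.6 and TDC at 84.2 to 127, with T cells at 20.6 to 23.7. Spearman correlations across genes, which are not independent replicates, were 0.922 to 0.968 between TDC libraries, 0.731 to 0.862 between TDC and DC and 0.630 to 0.686 between TDC and T cells.

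Zbtb46, the transcription factor whose locus carries the reporter (GRCm38 chromosome 2, 181387762 to 181459426, minus strand), was counted at 67.1 ± 40.9 CPM in DC, 7.95 ± 2.23 CPM in TDC and 1.28 ± 0.304 CPM in T cells. It was higher in TDC than in T cells (log2 fold change 2.64, SE 0.51, adjusted p = 0.00286) and lower in TDC than in DC (log2 fold change -3.08, SE 0.50, adjusted p = 0.00281). How the reporter allele alters the 3' end that these libraries count is not given in the sources used here, so this level checks the counted end only. Itgax, which encodes the integrin CD11c, was at 438 ± 206 CPM in DC, 103 ± 36.3 CPM in TDC and 0.687 ± 0.648 CPM in T cells. The CD3 chain gene Cd3e had 354 ± 36.0 CPM in T cells and 9.01 ± 3.52 CPM in TDC, with no reads in DC. The T cell receptor alpha constant gene Trac was at 1290.4 ± 276 CPM, 25.9 ± 13.9 CPM and 0.163 ± 0.282 CPM in T cells, TDC and DC. Cd4 was not called between TDC and either control (170.1 ± 98.9 CPM in TDC, 216 ± 69.1 CPM in T cells, 76.9 ± 41.9 CPM in DC, adjusted p = 0.694 and 0.240). The B cell receptor gene Cd79a had group means of 2.00 to 3.68 CPM, with 0.464 (T cell replicate 3) to 8.79 CPM (TDC replicate 1) in single libraries. The natural killer cell gene Ncr1 was not tested because it had reads in only 2 of the 9 libraries (8 in T cell replicate 1 and 42 in DC replicate 1).

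**Figure D1:**
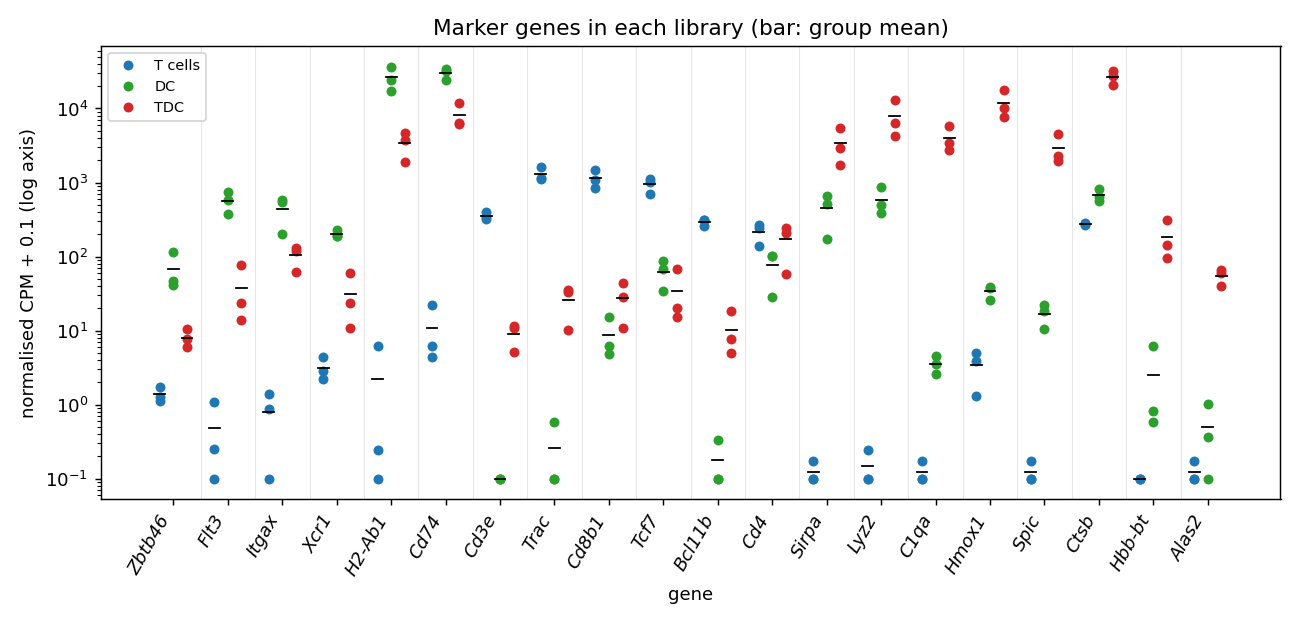
Normalised CPM plus 0.1 on a log axis for 20 genes, with a dot per library (n = 3 per group) and a bar at the group mean for T cells, DC and TDC. Cd3e lies at 354 CPM in T cells and 9.01 CPM in TDC, Zbtb46 at 67.1 CPM in DC and 7.95 CPM in TDC, and C1qa at 3.44 CPM in DC and 3976 CPM in TDC.

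The comparison of both controls asked how far the sorted T cells and DC differ from each other. DC carried high levels of MHC class II and myeloid genes such as Cd74 and Spi1 that were low or absent in T cells. Cd74, the invariant chain of MHC class II, was at 30348 ± 5209 CPM in DC and 10.9 ± 9.84 CPM in T cells (log2 fold change 11.44, SE 0.87, adjusted p = 1.39e-05). Il1b, H2-DMb1, Spi1 and Cd209a were among the genes with the largest positive change, all with no reads in T cells. Spi1, the myeloid transcription factor PU.1, reached 759.7 ± 272 CPM in DC, at least 13644-fold above T cells (adjusted p = 5.62e-06). Cd3g, Cd3e, Dapl1 and Cd40lg were among the genes with the largest negative change, all with no reads in DC, with Cd3g at 1532 ± 526 CPM in T cells (adjusted p = 2.32e-05).

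The gene lists written before the data were examined followed the sort labels. Of 26 genes of the T cell receptor complex and its proximal signalling, 24 were lower in DC over all genes and 24 adjusted over the list alone (camera adjusted p = 2.39e-22, and adjusted p = 0.0456 with an estimated correlation). The conventional DC core list had 26 of 28 members higher in DC, 27 adjusted over the list alone (camera adjusted p = 5.81e-17, and adjusted p = 0.00471 with an estimated correlation). The lists for both DC subsets had 16 of 20 (type 1) and 19 of 21 members (type 2) higher in DC, 16 and 21 adjusted over the list alone. Their camera adjusted p-values were 4.17e-12 and 2.65e-13, with adjusted p = 0.0504 and 0.0456 with an estimated correlation. All 14 tested genes of MHC class II presentation were higher in DC, also when adjusted over the list alone (camera adjusted p = 1.61e-12, and adjusted p = 0.0638 with an estimated correlation). Macrophage and monocyte genes were higher in DC for 19 of 26 members and lower for 1, 22 and 1 adjusted over the list alone (camera adjusted p = 1.07e-08, and adjusted p = 0.0456 with an estimated correlation). Adgre1 was at 155 ± 54.4 CPM in DC. In total 2269 genes were higher and 1237 lower in DC. With library size as the only scaling the higher share of the calls moved from 64.7% to 50.2%, with a shift of -0.30 in the median log2 fold change of all genes.

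TDC were compared with conventional T cells to ask how far they share a T cell transcriptome. Genes of the T cell receptor complex such as Trac and Cd3e were present in TDC at a small share of their level in T cells, whereas genes of macrophages, lysosomes, DC and erythroid cells were far above it. The 10 genes with the largest positive change were C1qc, Cd5l, C1qb, Fcna, Adgre1, Treml4, Slc11a1, Hpgd, C6 and Cd300a. C1qc, which encodes a chain of complement C1q, was at 7597 ± 3427 CPM in TDC with no reads in T cells, at least 136445-fold higher (adjusted p = 4.34e-06). The scavenger protein gene Cd5l reached 3013 ± 845 CPM and Adgre1, which encodes the macrophage marker F4/80, 2221 ± 839 CPM, again with no reads in T cells (adjusted p = 0.000292 and 4.34e-06). Slc11a1, a metal transporter of phagosomes, was at 1928 ± 303 CPM against no reads (adjusted p = 1.79e-06).

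The 10 largest falls were those of Cnga1, Samd3, Akap12, Klra1, Fgf13, Tnfsf11, Gimap7, Tcrg-C2, Klra7 and Gpr83. Gimap7, a lymphocyte GTPase gene, fell from 295 ± 109 CPM in T cells to 1.60 ± 2.42 CPM in TDC (log2 fold change -7.53, SE 1.22, adjusted p = 0.00109). Fgf13 fell from 46.3 ± 15.7 CPM to 0.149 ± 0.258 CPM (log2 fold change -8.02, SE 1.56, adjusted p = 0.00313). Samd3 was at 36.5 ± 15.8 CPM in T cells and 0.0372 ± 0.0644 CPM in TDC (adjusted p = 0.000225). Klra1 and Klra7 belong to a family of near-identical natural killer receptor genes, so their separate counts are uncertain. Among the T cell genes fixed in advance, Trac fell from 1290.4 ± 276 CPM to 25.9 ± 13.9 CPM (log2 fold change -5.64, SE 0.84, adjusted p = 0.000619) and Cd3e by a similar log2 fold change of -5.30 (SE 0.44, adjusted p = 5.96e-05). The cytotoxic T cell genes Cd8b1 and Gzmb fell as well, with log2 fold changes of -5.36 (SE 0.66, adjusted p = 0.000188) and -6.18 (SE 1.10, adjusted p = 0.00322). Foxp3, the regulatory T cell factor, was at 30.3 ± 4.76 CPM in T cells and 2.61 ± 1.65 CPM in TDC (log2 fold change -3.53, SE 0.69, adjusted p = 0.00304). Ifng was at 35.2 CPM in T cells and 1.03 CPM in TDC (log2 fold change -5.13, SE 0.98, adjusted p = 0.00469).

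T cell programmes were lower in TDC as groups. The receptor complex list had 24 of 26 members lower, and as many adjusted over the list alone (camera adjusted p = 1.25e-17, and adjusted p = 0.0762 with an estimated correlation). Its median log2 fold change was -5.31, and examples were Cd2 (-5.47, SE 0.53) and Lat (-5.48, SE 0.56). The single member that was higher was Lcp2, an adaptor also used by myeloid cells, at 836 ± 113 CPM in TDC and 426 ± 54.4 CPM in T cells, named after its values were seen. The Lcp2 call ended without T cell replicate 1 or 2 or TDC replicate 2 (adjusted p = 0.0561 to 0.0696), with library size as the only scaling (adjusted p = 0.300), with upper-quartile factors (0.0584) and without the filter on low counts (0.0599). T lineage transcription factors fell for 11 of 13 members, 11 adjusted over the list alone (camera adjusted p = 1.52e-08, and adjusted p = 0.0863 with an estimated correlation). Tcf7 was at a log2 fold change of -4.77 (SE 0.65) and Bcl11b at -4.84 (SE 0.67). Naive T cell genes were lower for 14 of 17 and higher for 1, 15 and 1 adjusted over the list alone (camera adjusted p = 3.43e-11, and adjusted p = 0.0753 with an estimated correlation). Regulatory T cell genes fell for 10 of 16, 14 adjusted over the list alone (camera adjusted p = 2.88e-07, and adjusted p = 0.0863 with an estimated correlation). Memory and effector genes went both ways, with 17 of 34 lower and 10 higher, 21 and 10 adjusted over the list alone (camera adjusted p = 0.00307, and adjusted p = 0.373 with an estimated correlation). Their higher members included Cd44, an adhesion receptor of many activated cells, at 1162 ± 176 CPM in TDC and 50.9 ± 8.31 CPM in T cells, and Zeb2 at 203 ± 74.3 CPM and 0.557 ± 0.289 CPM. Of the coreceptor genes Cd8a and Cd8b1 fell and Cd4 did not pass, 2 of 3 lower also when adjusted over the list alone (camera adjusted p = 0.00880, and adjusted p = 0.113 with an estimated correlation). The natural killer and innate-like T cell list had 14 of 22 lower and 4 higher, the same counts adjusted over the list alone (camera adjusted p = 0.000299, and adjusted p = 0.128 with an estimated correlation). Its higher members included Tyrobp and Fcer1g, signalling adaptors that myeloid cells also use.

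Myeloid programmes were higher in TDC than in T cells. The macrophage and monocyte list had 23 of 26 members higher and 1 lower, the same counts adjusted over the list alone (camera adjusted p = 5.58e-13, and adjusted p = 0.0651 with an estimated correlation). Apoe, a lipid carrier, was at 14424 ± 2902 CPM in TDC and 9.74 ± 4.86 CPM in T cells. Lysosome and phagocytosis genes were higher for 25 of 27, also when adjusted over the list alone (camera adjusted p = 1.12e-15, and adjusted p = 0.0753 with an estimated correlation). The cathepsin gene Ctsb took the most reads of any gene in each TDC library, at 26598 ± 5479 CPM against 276 ± 7.46 CPM. Pattern recognition receptors rose for 21 of 23, 22 adjusted over the list alone (camera adjusted p = 4.14e-10, and adjusted p = 0.0753 with an estimated correlation). Tlr2 (6.47, SE 0.43) and Tlr7 (5.96, SE 0.48) were among them. The conventional DC core list had 21 of 28 members higher and 2 lower, 21 and 4 adjusted over the list alone (camera adjusted p = 1.04e-05, and adjusted p = 0.0696 with an estimated correlation). Irf8 was at 782 ± 162 CPM and Flt3 at 37.6 ± 33.3 CPM in TDC. For the type 1 and type 2 DC lists 16 of 20 and 16 of 21 members were higher and 0 and 1 lower. Adjusted over the list alone 16 and 18 were higher and 1 and 1 lower. Their camera adjusted p-values were 4.43e-06 and 3.41e-06, with adjusted p = 0.117 and 0.0906 with an estimated correlation. MHC class II presentation was higher for 12 of 14 genes, also when adjusted over the list alone (camera adjusted p = 1.04e-06, and adjusted p = 0.131 with an estimated correlation). Cd74 was at 8173 ± 3152 CPM in TDC. Costimulatory ligands were higher for 7 of 11 and lower for 1, 8 and 1 adjusted over the list alone (camera adjusted p = 0.00424, and adjusted p = 0.0863 with an estimated correlation). Mature migratory DC genes had 10 of 17 higher and 3 lower, 12 and 3 adjusted over the list alone (camera adjusted p = 0.0946). Erythroid genes were higher for 14 of 15 members, 15 adjusted over the list alone (camera adjusted p = 9.23e-08, and adjusted p = 0.0863 with an estimated correlation). The heme synthesis gene Alas2 was at 55.3 ± 13.5 CPM in TDC and 0.0234 ± 0.0406 CPM in T cells.

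Over all genes 3204 were higher and 1654 lower in TDC than in T cells. Camera called 21 of the 32 lists with its preset correlation. With an estimated correlation camera called 0 at the adjusted threshold and 13 at an unadjusted p under 0.05. The fry test, which asks whether a list moves on balance in 1 direction, called 27. With library size as the only scaling the higher share of the calls moved from 66.0% to 42.9%, with a shift of -0.60 in the median log2 fold change. The count of lower genes was 1030 without T cell replicate 2 and 937 without TDC replicate 2.

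TDC were compared with conventional DC to ask how far they share a DC transcriptome. Macrophage genes such as C1qa, Hmox1 and Apoe were far higher in TDC, T cell genes such as Cd3e were present that had no reads in DC, and 14 of 28 genes of the conventional DC core list were lower. The 10 largest positive changes were those of Pcolce2, Slco2b1, Vstm4, Ptprm, Tmem37, Slc1a3, Slpi, Epor, Hs3st2 and Paqr9. Slpi, a secreted protease inhibitor, was at 2307 ± 1989 CPM in TDC and 0.0510 ± 0.0884 CPM in DC (log2 fold change 14.93, SE 1.29, adjusted p = 0.000161). Slco2b1, an organic anion transporter, and Epor, the erythropoietin receptor, were at 314 ± 211 CPM and 115 ± 21.6 CPM with no reads in DC (at least 5995-fold and 2196-fold higher, adjusted p = 0.000665 and 0.00135).

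The 10 largest falls were those of Ncald, Ptger3, Cdh17, Mmp12, Mab21l3, Gfod1, Bcas1, Il1r2, Scn3a and Skint3. Mmp12, a secreted metalloproteinase, fell from 193 ± 91.8 CPM in DC to 2.85 ± 1.61 CPM in TDC (log2 fold change -6.08, SE 0.61, adjusted p = 0.000701). Ncald fell from 12.0 ± 3.53 CPM to 0.122 ± 0.0532 CPM (log2 fold change -6.56, SE 0.89, adjusted p = 0.00116). Cdh17 fell from 17.4 ± 5.21 CPM to 0.230 ± 0.266 CPM (log2 fold change -6.18, SE 1.13, adjusted p = 0.00847). Flt3, the growth factor receptor of DC, fell from 568 ± 178 CPM to 37.6 ± 33.3 CPM (log2 fold change -3.92, SE 0.87, adjusted p = 0.0139). The chemokine receptor gene Xcr1 of type 1 DC fell from 203 ± 22.5 CPM to 31.4 ± 25.9 CPM (log2 fold change -2.69, SE 0.57, adjusted p = 0.0108). H2-Ab1 and Cd74 did not pass, with 3404 ± 1410.4 CPM in TDC and 26289 ± 9814 CPM in DC for H2-Ab1 (adjusted p = 0.128) and 8173 ± 3152 CPM and 30348 ± 5209 CPM for Cd74 (adjusted p = 0.0546). Libraries of TDC and DC did not overlap for either gene, so the lack of a call does not mean like levels. The fit estimated the spread with the T cell libraries included, where H2-Ab1 ran from 0 to 6.12 CPM. Whether that kept the genes from a call was not tested. Calls that ended when 1 library was left out were those of Flt3 (without TDC replicate 2: adjusted p = 0.0677), Mab21l3 (without TDC replicate 2: adjusted p = 0.0770), Il1r2 (without TDC replicate 2 or 3: adjusted p = 0.0686 to 0.0744), Ptger3 (without DC replicate 1 or TDC replicate 1, 2 or 3: adjusted p = 0.0524 to 0.0855), Scn3a (without DC replicate 1 or 2 or TDC replicate 2: adjusted p = 0.0643 to 0.0903), Skint3 (without DC replicate 1 or 2 or TDC replicate 1 or 2: adjusted p = 0.0526 to 0.126) and Bcas1 (without DC replicate 1, 2 or 3 or TDC replicate 1, 2 or 3: adjusted p = 0.0582 to 0.126). Without the filter on low counts, adjusted p was 0.0647 for Flt3, 0.112 for Il1r2 and 0.112 for Ptger3.

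Most macrophage and lysosome genes were higher in TDC than in DC. The macrophage and monocyte list had 21 of 26 members higher and 1 lower, the same counts adjusted over the list alone (camera adjusted p = 1.35e-14, and adjusted p = 0.0231 with an estimated correlation). C1qa rose from 3.44 ± 0.947 CPM to 3976 ± 1643 CPM (log2 fold change 10.17, SE 0.62, adjusted p = 4.09e-05). Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, rose from 33.8 ± 7.30 CPM to 11948 ± 5261 CPM (log2 fold change 8.47, SE 0.67, adjusted p = 0.000117). Apoe rose from 179.8 ± 59.1 CPM to 14424 ± 2902 CPM (log2 fold change 6.33, SE 0.51, adjusted p = 0.000117). Spic, a transcription factor of splenic red pulp macrophages, was at 2887 ± 1376 CPM in TDC and 16.9 ± 5.83 CPM in DC. Lysosome and phagocytosis genes were higher for 18 of 27 members and lower for 1, 19 and 3 adjusted over the list alone (camera adjusted p = 1.12e-10, and adjusted p = 0.129 with an estimated correlation). Ctsb was at 26598 ± 5479 CPM against 668 ± 132 CPM and Ctsd at 5199 CPM against 58.7 CPM. Pattern recognition receptors were higher for 7 of 23 and lower for 2, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0203, and adjusted p = 0.421 with an estimated correlation). Erythroid genes were higher for 12 of 15 and lower for 1 (Tspan33, named after its values were seen), 13 and 1 adjusted over the list alone (camera adjusted p = 1.01e-08, and adjusted p = 0.129 with an estimated correlation). The Tspan33 call ended without T cell replicate 1, 2 or 3 or DC replicate 1 or 3 or TDC replicate 1, 2 or 3 (adjusted p = 0.0557 to 0.165).

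Genes of conventional DC were lower in TDC than in DC. The core list had 14 of 28 members lower and 2 higher, 20 and 3 adjusted over the list alone (camera adjusted p = 9.57e-10, and adjusted p = 0.0231 with an estimated correlation). Nfil3 was at a log2 fold change of -3.14 (SE 0.37) and Dpp4 at -3.37 (SE 0.54). Type 1 DC genes were lower for 10 of 20 and higher for 1, 14 and 1 adjusted over the list alone (camera adjusted p = 1.05e-07, and adjusted p = 0.164 with an estimated correlation). Cd24a (-2.17, SE 0.31) was among them. Cadm1 rose (2.18, SE 0.39). Type 2 DC genes went both ways, 6 of 21 lower and 3 higher, 8 and 5 adjusted over the list alone (camera adjusted p = 0.0449, and adjusted p = 0.4996 with an estimated correlation). Clec4a4 fell from 148 ± 81.1 CPM to 5.26 ± 3.17 CPM and Cd209a from 676 ± 224 CPM to 31.5 ± 26.5 CPM. Sirpa rose from 449 ± 249.7 CPM to 3369 ± 1909.5 CPM and Lyz2, the macrophage lysozyme, from 586 ± 256 CPM to 7944 ± 4676 CPM. Genes of mature migratory DC fell for 11 of 17, 13 adjusted over the list alone (camera adjusted p = 2.23e-10, and adjusted p = 0.0794 with an estimated correlation). Ccr7 (-3.68, SE 0.39) and Il12b (-3.98, SE 0.51) were among them. MHC class II presentation was lower for 5 of 14 genes and higher for 2, 11 and 2 adjusted over the list alone (camera adjusted p = 1.04e-06, and adjusted p = 0.280 with an estimated correlation). Its lower members included H2-Oa (-4.48, SE 0.70) and H2-Ob (-3.97, SE 0.62). The lysosomal protease gene Lgmn was higher at 1488 ± 571 CPM against 58.2 ± 32.0 CPM. Costimulatory ligands were lower for 3 of 11 and higher for 1, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0455, and adjusted p = 0.282 with an estimated correlation). Icosl and Cd40 were lower and Cd86 was higher, at 1483 ± 189 CPM against 233 ± 48.1 CPM.

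Genes of the T cell receptor complex were higher in TDC than in DC, whereas the lists of other T cell genes below did not pass. Those lists hold genes that DC express too, such as Ccr7 at 1084 CPM and Tcf7 at 62.4 CPM in DC. Among members higher in T cells than in DC by a log2 fold change of at least 2, TDC had like median positions toward T cells. These were 2.19% (receptor complex), 2.95% (transcription factors), 2.44% (naive) and 1.30% (memory and effector). Quartiles of the naive genes were 1.06% and 3.65%, so the signal was not confined to receptor genes. Lower quartiles were -3.62% for transcription factors and -0.528% for memory and effector genes, so those lists alone do not show it. The receptor complex list had 21 of 26 members higher and 0 lower, 24 and 1 adjusted over the list alone (camera adjusted p = 1.12e-10, and adjusted p = 0.182 with an estimated correlation). Trac (log2 fold change 7.52, SE 1.02, adjusted p = 0.00127) and Trbc2 (log2 fold change 6.51, SE 1.05, adjusted p = 0.00280) were among them. Trbc1 and Trbc2 are near-identical copies, so how reads were shared between them is uncertain. Naive T cell genes were higher for 6 of 17 and lower for 1 (Ccr7), 7 and 2 adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.0766). T lineage factors were higher for 3 of 13 and lower for 2, 5 and 4 adjusted over the list alone (camera adjusted p = 0.740). Bcl11b was at 10.2 ± 6.99 CPM in TDC and 0.0765 ± 0.133 CPM in DC and Tcf7 at 34.6 ± 29.4 CPM and 62.4 ± 26.4 CPM (adjusted p = 0.364). The coreceptor, memory and effector, regulatory and natural killer lists did not pass as lists against DC. Coreceptors had 0 of 3 higher and 1 lower, 1 and 1 adjusted over the list alone (camera adjusted p = 0.816). Memory and effector genes had 6 of 34 higher and 4 lower, 9 and 6 adjusted over the list alone (camera adjusted p = 0.952). Regulatory T cell genes had 5 of 16 higher and 3 lower, 5 and 5 adjusted over the list alone (camera adjusted p = 0.786). Natural killer and innate-like genes had 1 of 22 higher and 4 lower, 2 and 7 adjusted over the list alone (camera adjusted p = 0.0629).

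Over all genes 1404 were higher and 677 lower in TDC than in DC, and camera called 15 of the 32 lists, 2 of them also with an estimated correlation. With library size as the only scaling the higher share of the calls moved from 67.5% to 53.1%, with a shift of -0.30 in the median log2 fold change. The count of higher genes was 897 without TDC replicate 2, and the count of lower genes was 418 without DC replicate 1, 447 without TDC replicate 1 and 293 without TDC replicate 2. The lower type 1 DC genes numbered 5 without DC replicate 1, 5 without DC replicate 3 and 6 without TDC replicate 2. The lower mature migratory genes numbered 7 without DC replicate 1, 7 without TDC replicate 1 and 5 without TDC replicate 2. With other settings the lower MHC class II genes numbered 9 (library size only), 8 (DESeq2 Wald test) and 11 (limma-voom). They numbered 9 without T cell replicate 2 and 3 without TDC replicate 2.

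Genes above both controls are not given by any blend of the 2 control profiles. TDC were above both T cells and DC for 1039 genes, and among the 10 with the largest changes were Pcolce2, Slco2b1, Vstm4, Slc1a3, Hs3st2, Paqr9, Ms4a8a, Gpd1, Mrap and Vnn3. Pcolce2, an enhancer of procollagen processing, was at 348 ± 110.1 CPM, Vstm4 at 301 ± 74.1 CPM and the glutamate transporter gene Slc1a3 at 236 ± 32.1 CPM in TDC with no reads in either control. Slc1a3 was at least 4243-fold above T cells and 4508-fold above DC (adjusted p = 1.69e-05 and 0.000149). Paqr9 was at 340.4 ± 58.3 CPM in TDC and 0.0128 ± 0.0221 CPM in DC. Members above both controls numbered 21 of 26 in the macrophage and monocyte list, 17 of 27 in the lysosome and phagocytosis list, 12 of 15 in the erythroid list and 7 of 23 in the pattern recognition list. They included Spic, C1qa, Hmox1 and Lyz2 of the macrophage list, Ctsb, Ctsd and Lamp1 of the lysosome list and Cd14, Tlr2 and Tlr4 of the receptor list. Simulated unchanged groups gave 0 such genes in each of 20 simulations. All groups followed the T cell profile there and hardly any gene was called, so that outcome was all but fixed and does not test the set. The count in the real data was 642 without TDC replicate 2.

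**Figure D2:**
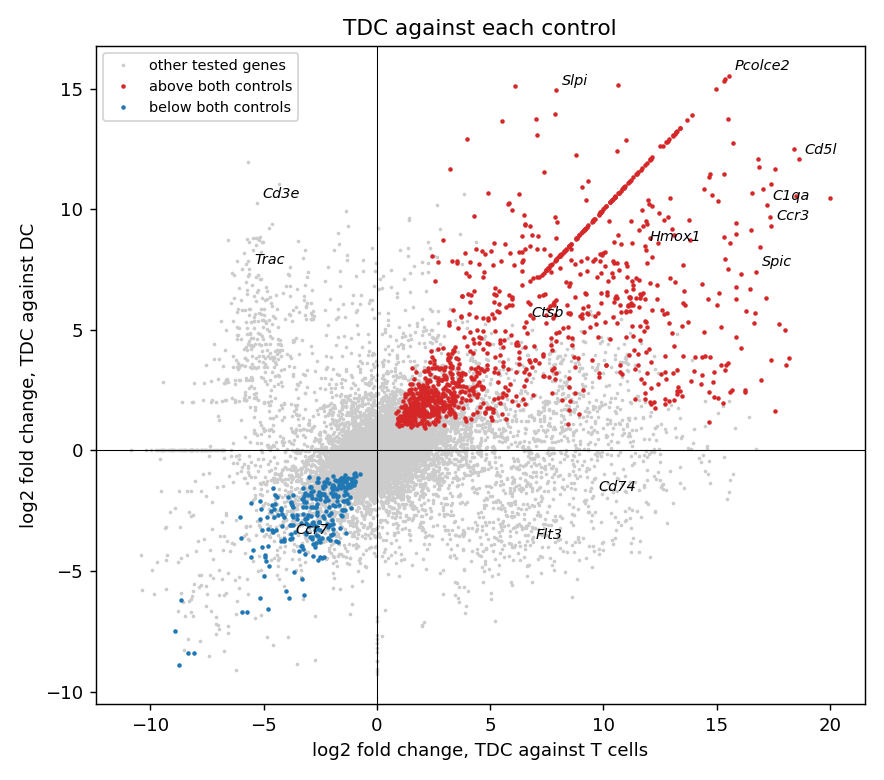
Log2 fold change of TDC against T cells (x axis) and of TDC against DC (y axis) for the 14708 tested genes, with the 1039 genes above both controls in red and the 248 below both in blue. Genes without reads in both controls lie on the diagonal, where the fitted values depend on the prior count.

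TDC were below both controls for 248 genes. The 10 with the largest changes were Krtcap3, Hook1, Tnfrsf4, Itgb3, Ccl5, Ccr7, Gpr183, Pglyrp1, Mirt1 and Tec. Ccr7, the receptor that guides T cells and DC to lymph nodes, was at 84.3 ± 35.5 CPM in TDC, 1194 ± 289 CPM in T cells and 1084 ± 183 CPM in DC (log2 fold change -3.82, SE 0.39, adjusted p = 6.09e-05 against T cells and log2 fold change -3.68, SE 0.39, adjusted p = 0.000364 against DC). Gpr183, an oxysterol receptor that positions these cells, was at 20.1 ± 13.8 CPM, 347 ± 158 CPM and 258 ± 145 CPM in the same order (adjusted p = 0.000768 and 0.00348). The chemokine gene Ccl5 was at 12.7 ± 6.03 CPM in TDC, 218 ± 116 CPM in T cells and 170.2 ± 72.8 CPM in DC (adjusted p = 0.000341 and 0.00172). The count was 91 without TDC replicate 2 and 520 with library size as the only scaling, and the calls against DC ended for Krtcap3 (without TDC replicate 2: adjusted p = 0.0570), Tnfrsf4 (without TDC replicate 2: adjusted p = 0.0642) and Hook1 (without T cell replicate 1, 2 or 3 or DC replicate 1 or 3 or TDC replicate 1 or 2: adjusted p = 0.0588 to 0.148). The call of Hook1 against T cells ended as well without TDC replicate 2 (adjusted p = 0.0589).

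The level of TDC between both controls was described for list genes that differed between T cells and DC by a log2 fold change of at least 2. For 84 genes of the DC lists the median position was 22.3% of the way from T cells to DC, and the medians per TDC library were 16.3%, 18.7% and 28.8%. The median position was 39.3% for type 2 DC genes, 24.0% for the DC core, 20.4% for type 1 DC genes, 13.9% for MHC class II presentation and 12.7% for mature migratory DC genes, and 15 of the 84 genes lay above the DC level. Quartiles were 8.16% and 57.2% for the 84 genes. For type 2 DC genes they were 7.05% and 326%, with 8 of 19 above the DC level, among them Lyz2, which is also in the macrophage list. The medians therefore do not rank how near TDC lie to each DC subset. For 58 genes of the T cell lists the median position was 2.03% of the way from DC to T cells, and the medians per library were 1.59%, 0.754% and 2.98%. The medians of the T cell lists were 2.19% for the receptor complex, 2.95% for transcription factors, 2.44% for naive genes and 1.30% for memory and effector genes. Genes that differed from both controls and lay between them numbered 290 over all genes, 172 without TDC replicate 2 and 193 without TDC replicate 3.

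Shared calls were counted against both controls. Of the 2269 genes higher in DC than in T cells, 1746 were also higher in TDC than in T cells, where independent lists would share 494, and of the 1237 lower genes 812 were shared, where independent lists would share 139. Irf8 at 789 ± 246 CPM in DC and 782 ± 162 CPM in TDC and Spi1 at 759.7 ± 272 CPM and 391 ± 88.8 CPM were among the shared higher genes. So were Lyz2 of the macrophage list, at 586 ± 256 CPM and 7944 ± 4676 CPM, and Flt3, at 568 ± 178 CPM and 37.6 ± 33.3 CPM. The overlap was taken against T cells alone and therefore does not measure a shared DC programme. Against DC, 307 of the genes higher in T cells were also higher in TDC (118 for independent lists) and 365 of the genes lower in T cells were also lower in TDC (104). Cd28 at 426 ± 126 CPM in T cells and 17.1 ± 8.31 CPM in TDC and Lef1 at 647 CPM and 15.8 CPM were among the former. Simulated groups that all followed the profile of 1 control shared a mean of 0 to 0.05 genes in 20 simulations. Hardly any gene is called in that setting, so it cannot measure how far shared controls raise the overlap of groups that do differ. The 3 control libraries of a group cannot be split into groups of at least 2, so part of the excess may come from the shared controls. Genes that moved in opposite directions from T cells in DC and TDC numbered 10 (higher in DC, lower in TDC) and 34 (lower in DC, higher in TDC). Independent lists would share 255 and 269, and part of this shortfall may come from the shared controls as well. The shared lower genes numbered 512 without T cell replicate 2 in the comparison with T cells, and 209 without DC replicate 1 and 180 without TDC replicate 2 in the comparison with DC.

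Markers of other cells that a spleen sort could hold were examined in the same way. B cell genes were mixed, with 7 of 17 higher and 2 lower in TDC than in T cells (7 and 3 adjusted over the list alone, camera adjusted p = 0.207). Against DC 2 were higher and 3 lower (3 and 3, camera adjusted p = 0.608). Ighm, the immunoglobulin mu chain gene, was at 135 ± 89.5 CPM in TDC, 1095 ± 340.1 CPM in T cells and 489 ± 124 CPM in DC (log2 fold change -3.02, SE 0.49, adjusted p = 0.00111 against T cells and log2 fold change -1.86, SE 0.47, adjusted p = 0.0251 against DC). Its call against DC ended without DC replicate 1 or 2 or TDC replicate 1 or 2 (adjusted p = 0.0556 to 0.0996). Blnk, an adaptor that macrophages also use, was at 163 ± 25.3 CPM in TDC and 5.46 ± 1.63 CPM in DC. Ms4a1, which encodes CD20, fell from 204 ± 20.6 CPM to 14.9 ± 12.0 CPM. Plasmacytoid DC genes were higher for 12 of 18 and lower for 2 against T cells (14 and 2 adjusted over the list alone, camera adjusted p = 0.00424, and adjusted p = 0.168 with an estimated correlation). In the comparison with DC 3 were higher and 3 lower than in DC (3 and 5 adjusted over the list alone, camera adjusted p = 0.181). Siglech was at 17.1 ± 12.0 CPM in TDC and 13.6 ± 1.71 CPM in DC. Of the 17 genes of the neutrophil list only 5 had enough reads to be tested. Of these 5 genes 4 were higher than in T cells, also when adjusted over the list alone (camera adjusted p = 0.00909, and adjusted p = 0.0863 with an estimated correlation). Of the same 5 genes 1 was higher and 1 lower than in DC (1 and 2 adjusted over the list alone, camera adjusted p = 0.916). Cxcr2 was the higher gene, at 7.25 ± 5.07 CPM, and Mmp9 the lower, at 3.18 ± 0.986 CPM against 33.5 ± 20.3 CPM. The platelet list, with 4 of its 13 genes tested, had 2 of these higher and 1 lower than in either control, also when adjusted over the list alone (camera adjusted p = 0.499 against T cells and 0.622 against DC). Itgb3 was lower and Clec1b higher, at 256 ± 119.7 CPM against 2.77 ± 3.20 CPM in DC. The Clec1b call against DC had an adjusted p = 0.118 without the filter on low counts. Of the 16 stroma and endothelium genes only 4 had enough reads to be tested, so these counts do not describe the whole list. The tested genes were higher for 3 of 4 against T cells, 4 adjusted over the list alone (camera adjusted p = 0.0254, and adjusted p = 0.171 with an estimated correlation), and for 3 against DC, also when adjusted over the list alone (camera adjusted p = 0.0449, and adjusted p = 0.282 with an estimated correlation). Cxcl13 was at 51.4 ± 32.0 CPM, with no reads in either control.

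**Figure D3:**
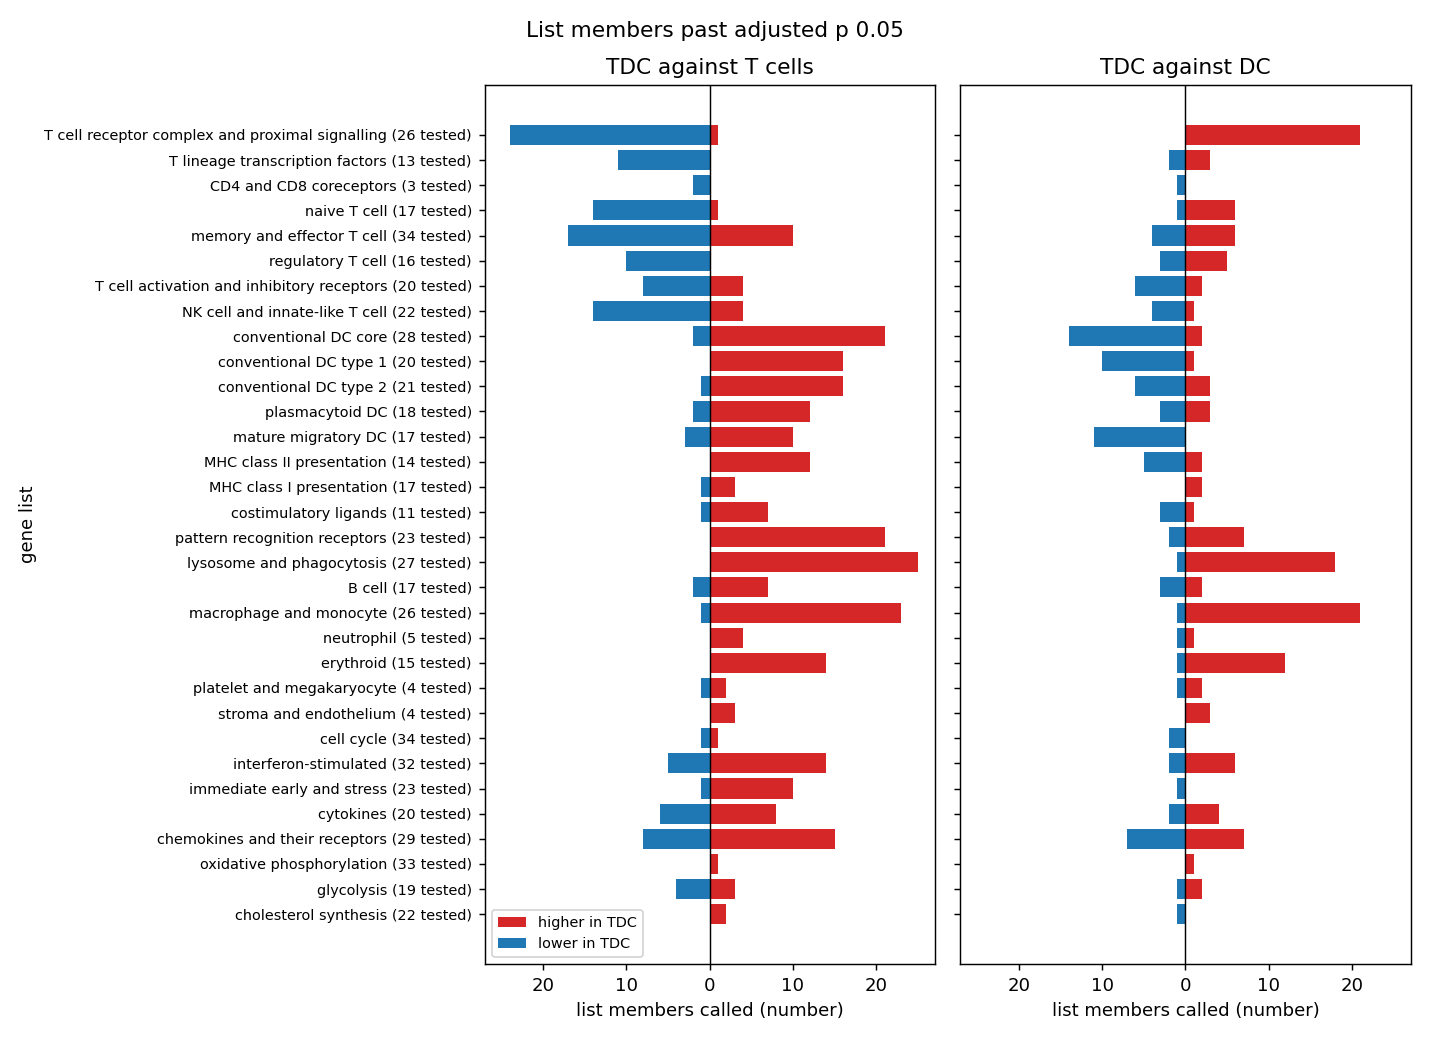
Number of members of 32 gene lists called higher or lower in TDC against T cells and against DC (edgeR, adjusted p under 0.05 over all genes), drawn as bars to the right for higher and to the left for lower. The macrophage and monocyte list has 23 members higher than T cells and 21 higher than DC, and the T cell receptor list 24 lower than T cells and 21 higher than DC.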

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

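All alternatives in this part were planned before the data were examined. With library size as the only scaling the genes lower in DC than in T cells numbered 1886, those lower in TDC than in T cells 3321, those below both controls 520 and the shared lower genes of DC and TDC 1427. This scaling moved the median log2 fold change of all genes by -0.30 to -0.60, and upper-quartile factors moved it by -0.11 to -0.25. The DESeq2 Wald test called 2127 genes higher and 1267 lower in TDC than in DC, 474 below both controls, 502 between them, and 529 higher and 642 lower genes shared by T cells and TDC against DC, and limma-voom called 1051 lower in TDC than in DC and 668 of the latter kind. Against a log2 fold change of 1, glmTreat called 818 genes lower in DC than in T cells, 921 lower in TDC than in T cells, 908 higher and 310 lower in TDC than in DC, 678 above both controls, 82 below both, 171 between, 534 shared lower genes of DC and TDC, and 192 higher and 173 lower genes shared by T cells and TDC. Against that fold change the lower type 1 DC genes numbered 5 and the lower mature migratory genes 7 in TDC against DC. With an estimated correlation camera called 6, 0 and 2 lists (DC against T cells, TDC against T cells, TDC against DC; 15, 13 and 7 at an unadjusted p under 0.05), against 23, 27 and 15 with fry. Why the tools differed was not tested.

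Leaving out a library or a replicate number gave 1283 to 2492 higher and 552 to 1384 lower genes for DC against T cells, 1984 to 3585 and 652 to 1945 for TDC against T cells and 548 to 1365 and 81 to 611 for TDC against DC. It gave 401 to 982 genes above both controls, 29 to 249 below both and 85 to 259 between. The shared genes ran from 1018 to 1855 (higher) and 309 to 957 (lower) for DC and TDC against T cells, and from 146 to 275 and 44 to 309 for T cells and TDC against DC. The lowest counts came without replicate 1 or replicate 2 in every group, where 6 libraries were left. Of the genes above both controls, 392 were called without replicate 1 in every group. The macrophage and monocyte list had 15 to 21 members above both controls, the erythroid list 3 to 13, the lysosome list 10 to 16 and the pattern recognition list 3 to 8. The lower genes in TDC against DC numbered 0 to 9 for MHC class II presentation, 4 to 15 for the DC core, 1 to 10 for type 1 DC and 3 to 10 for mature migratory DC. The median position of TDC ran from 16.6 to 27.7% for DC genes and from 1.54 to 2.69% for T cell genes. When single libraries were left out, camera with its preset correlation called 19 to 22 lists for DC against T cells and 21 to 22 for TDC against T cells. For TDC against DC it called 11 (without DC replicate 2) to 16. The 1 named gene result that turned with a call was not called with all libraries in: for Bcas1, TDC against T cells gave log2 fold changes of -1.68 without T cell replicate 3 and 4.83 without T cell replicate 2 (adjusted p = 0.372 and 0.0491).

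Same-numbered libraries of the 3 populations share a code in the column names and the number of mice, and Hspa1a and Hspa1b were lowest in replicate 1 of each population. That they come from the same pool of mice is not stated in the labels and stays open, so the numbers were not used as pairs. Deviations of same-numbered libraries from their group means correlated at -0.38 to 0.22, 2 of 9 pairs lay over 0.1, and 0 libraries correlated best with their own number in both other groups. In single groups each of the 3 T cell libraries correlated best with its own number among the DC libraries, and 2 DC libraries did so among the T cell libraries, against 0 in the 4 directions that include TDC. With the replicate number as a block (replicate block) the genes lower in TDC than in DC numbered 431, those below both controls 156, the shared lower genes of T cells and TDC 228 and the lower mature migratory genes in TDC against DC 7. Over 145 named genes and all settings, 9059 of the gene results kept their call or lack of a call, 98 of them uncalled values that changed sign, 301 lost the call, 134 gained one and 1 turned with a call.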

Other observations

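The counts and tests of gene lists in this part were fixed before the data were examined, whereas the tests of explanations and the splits were chosen after the results had been seen. Interferon-stimulated genes had 14 of 32 higher and 5 lower, 16 and 5 adjusted over the list alone in TDC against T cells (camera adjusted p = 0.0919). Against DC they had 6 of 32 higher and 2 lower, 10 and 3 adjusted over the list alone (camera adjusted p = 0.0449, and adjusted p = 0.336 with an estimated correlation). Cxcl10, a chemokine gene induced by interferon, was at 148 ± 11.8 CPM in TDC, 2.52 ± 0.805 CPM in T cells and 21.6 ± 9.20 CPM in DC (edgeR adjusted p = 1.40e-05 and 0.00176). The antiviral gene Rsad2 was at 79.2 ± 20.2 CPM, 3.66 ± 1.36 CPM and 12.0 ± 3.58 CPM in the same order. Cytokine genes had 8 of 20 higher and 6 lower, 11 and 7 adjusted over the list alone against T cells (camera adjusted p = 0.499). The same list had 4 of 20 higher and 2 lower, 4 and 3 adjusted over the list alone against DC (camera adjusted p = 0.622). Il18 was at 604 ± 271 CPM in TDC and 40.0 ± 14.3 CPM in DC. Ltb, which encodes lymphotoxin beta, was at 44.0 ± 26.4 CPM in TDC, 1094 ± 257 CPM in T cells and 436 ± 149.7 CPM in DC. Chemokines and their receptors had 15 of 29 higher and 8 lower, 16 and 9 adjusted over the list alone against T cells (camera adjusted p = 0.499). In the comparison with DC they had 7 of 29 higher and 7 lower, 7 and 9 adjusted over the list alone (camera adjusted p = 0.162). T cell activation and inhibitory receptors had 4 of 20 higher and 8 lower, 4 and 13 adjusted over the list alone against T cells (camera adjusted p = 0.00880, and adjusted p = 0.128 with an estimated correlation). Their counts against DC were 2 of 20 higher and 6 lower, 3 and 6 adjusted over the list alone (camera adjusted p = 0.0449, and adjusted p = 0.282 with an estimated correlation). The nuclear receptor gene Nr4a2 was at 4.07 CPM in TDC and 89.0 CPM in DC (adjusted p = 0.000468).

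Immediate early and stress genes had 10 of 23 higher and 1 lower, 11 and 1 adjusted over the list alone in TDC against T cells (camera adjusted p = 0.0104, and adjusted p = 0.477 with an estimated correlation). Zfp36, which encodes an mRNA decay factor, was at 4239 ± 1556 CPM in TDC and 528 ± 57.9 CPM in T cells. Against DC 1 of 23 was lower, 0 adjusted over the list alone (camera adjusted p = 0.257). Cell cycle genes were lower in TDC than in DC as a list with 2 of 34 members called, 0 adjusted over the list alone (camera adjusted p = 5.96e-08, and adjusted p = 0.282 with an estimated correlation). Mki67, a proliferation marker, was at 18.4 ± 7.83 CPM in TDC, 63.5 ± 41.7 CPM in DC and 10.2 ± 3.32 CPM in T cells (edgeR adjusted p = 0.0522 against DC and 0.253 against T cells). Against T cells 1 cell cycle gene was higher and 1 lower, 0 and 0 adjusted over the list alone (camera adjusted p = 0.659). Class I presentation genes had 3 of 17 higher and 1 lower, 3 and 1 adjusted over the list alone against T cells. They had 2 of 17 higher and 0 lower, 2 and 1 adjusted over the list alone against DC (camera adjusted p = 0.481 and 0.942). Of 33 oxidative phosphorylation genes Sdhc alone was called, at 159.7 ± 70.8 CPM in TDC, 51.6 ± 12.9 CPM in T cells and 35.5 ± 9.35 CPM in DC (camera adjusted p = 0.0906 and 0.695 for the list). Adjusted over the list alone, it was called against DC but not against T cells. Glycolysis genes had 3 of 19 higher and 4 lower, 3 and 4 adjusted over the list alone against T cells (camera adjusted p = 0.659). Against DC glycolysis genes had 2 of 19 higher and 1 lower, 2 and 1 adjusted over the list alone (camera adjusted p = 0.741). Cholesterol synthesis genes had 2 of 22 higher against T cells and 1 lower against DC, the same counts adjusted over the list alone (camera adjusted p = 0.973 and 0.695). Median, mean and camera direction differed in sign only for lists that did not pass. With median and mean log2 fold change and camera direction, these were cell cycle (0.10, 0.32, down), glycolysis (0.04, 0.61, down) and cholesterol synthesis (0.16, 0.23, down) against T cells. Against DC they were T lineage transcription factors (-0.82, 0.99, down), CD4 and CD8 coreceptors (1.14, 0.04, down), memory and effector T cell (0.34, 0.75, down), MHC class I presentation (-0.09, 0.03, down), neutrophil (0.30, 1.48, down), chemokines and their receptors (-0.73, 0.09, down), glycolysis (0.07, -0.24, down) and cholesterol synthesis (0.08, 0.06, down), and in DC against T cells stroma and endothelium (0.00, 2.04, up), glycolysis (-0.03, 0.85, down) and cholesterol synthesis (-0.11, 0.17, up).

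The macrophage genes in TDC are the pattern a biologist would follow up first. A blend of T cell and DC RNA puts no gene above both controls, and 21 of 26 macrophage list members lay above both. The scaling between groups is argued against as well, since 20 members were above both with library size only, and so are T cells of ordinary RNA content that keep their transcripts and add macrophage genes, since the genes private to T cells lay at a median of 2.43% of the T cell level, although RNA per cell was not measured. Splenic macrophages in the sorted TDC, or RNA of them carried along, and a macrophage-like programme of the TDC themselves cannot be told apart here, since either would give the high share of reads that was seen: the list took at least 7.81% of the reads in each TDC library, against 0.316% to 0.498% in DC and at most 0.0912% in T cells, with Apoe at 14424 CPM, Hmox1 at 11948 CPM and C1qb at 9670.2 CPM. The gates that could remove macrophages are not given in the sources used here, and 16 of the 26 members were at 10 CPM or more in DC and 8 stand in another list, although 9 of the members above both were under 10 CPM in DC.

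Genes private to T cells, chosen at 50 CPM or more in T cells and at most 1% of that in DC, lay in TDC at a small share of the T cell level. Cd4 and the 10 of 34 memory and effector genes that were higher in TDC did not, but they lay outside this set. Cd4 was at 76.9 CPM in DC, and 0 of the 93 private genes were above the T cell level in TDC. In DC 10 memory and effector genes were higher than in T cells as well. Outside the receptor complex list stand receptor variable segments such as Trbv13-2 at 2.99%. Non-receptor genes such as Gimap4 at 1.84%, Lef1 at 2.45% and Igfbp4 at 3.77% stand there too. A loss of receptor complex genes alone is argued against, since genes private to T cells outside that list had a median share of 2.44%. One source of T cell RNA at a small share, such as a minority of T cells, may account for the pattern in these genes: 84.9% of the 93 private genes lay within 2-fold of their median share, with library medians of 2.31%, 1.09% and 3.80%. Of 218 genes private to DC 31.2% did so around a median of 39.9%. These were chosen against T cells alone and included macrophage list genes such as Adgre1 and Lyz2, and 68 lay above the DC level in TDC. Their median and spread therefore do not measure a share of DC RNA. Dok2 at 41.1%, Smpd5 at 47.6%, Art2b at 22.4% and Ikbke at 10.6% of the T cell level were the genes private to T cells above 10%. Whether single cells carry both programmes cannot be read from pooled RNA and was not tested.

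Erythroid genes were above both controls for 12 members of their list. RNA of erythroid cells, in the sort or taken up by phagocytes, and an erythroid programme of the TDC themselves cannot be told apart by that count, since each would give it. Free erythroid RNA shared by all sorted populations is argued against, since the lowest TDC library held 24.9 times the Hbb-bs level of the highest control library. Hbb-bs and Hbb-bt are near-identical, so their split is uncertain, but Alas2 at 55.3 CPM in TDC and 0.391 CPM in DC does not share that limit. Cells in the sort and uptake of red cells were not told apart by any test.

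Cd4 was at 57.6, 209 and 243 CPM in the TDC libraries, 78.6% of the T cell mean. The DC libraries held it at 102, 28.6 and 100 CPM, so this level is not specific to T cell RNA. Hspa1a, an inducible heat shock gene with the near-identical copy Hspa1b, was low in replicate 1 of each population, at 1.34 CPM in T cells, 39.2 CPM in DC and 39.1 CPM in TDC, against 72.6 and 85.9 CPM, 551 and 917 CPM, and 1488 and 895 CPM in the other replicates.

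Other splits of the libraries were counted for each result. The 6 libraries of a pair of groups make 10 splits, too few for a share under 0.05, and 1 of 10 splits, the real one, reached the real count in each comparison. The real splits called 3506 genes (DC against T cells), 4858 (TDC against T cells) and 2081 (TDC against DC), and the highest of the other splits 0 in each case by edgeR. For the list tests the real splits called 20, 21 and 15 lists and the highest of the others 17, 17 and 13. For the sets over 3 groups 60 of 840 possible labellings of the 9 libraries were drawn, and 1 of 60, the real one, gave as many genes in each set, a share under 0.05. The other splits and nearly all other labellings put libraries of different populations in 1 group, which widens the spread within groups. Where counts were low there, they show that libraries separate by population and do not test the sets themselves. Counts for the list tests and for several shared sets were not low. List calls and shared genes can therefore arise in large number when populations are mixed. The real value and the highest of the others were 1039 and 1 above both controls, 248 and 1 below both, and 290 and 0 between. They were 1746 and 1247 for higher and 812 and 396 for lower genes shared by DC and TDC, and 307 and 46 for higher and 365 and 268 for lower genes shared by T cells and TDC.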
